A study of Mus musculus with 2 samples.

How the data were processed

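RNA of differentiated small proliferative adipocytes (SPAD) and differentiated stromal vascular cells (SVCD) was labelled with Cy3 from 30 ng each and hybridised to 1 Agilent array per group, per the labels. Nothing in the labels says how many animals or cultures each RNA came from. Both arrays lay on the same slide and carry the same scan and extraction times, so slide and scan did not differ between the groups. Spots were quantified with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. The deposited scanner files give each spot's processed intensity on a linear scale, background-subtracted, per the file headers. The authors also deposited a table of processed values on a log2 scale, in which the SPAD and SVCD columns were exactly opposite in sign for all 39485 probes (to within 0.0001), with medians of 0.16 and -0.16. Set against the scanner files, the difference of these columns equalled the log2 difference of processed intensity plus a constant shift of 0.12, so each probe had been centred on both arrays and only differences can be read from the table. The shift from scaling to the 75th percentile here was 0.13. How the authors chose their scaling is not given in the sources used here.

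The main values were log2 processed intensity minus its 75th percentile over the non-control probes of the same array. That percentile was an intensity of 622 on the SPAD array and 678 on the SVCD array. Of 44397 spots per array, 1377 were controls and left out, as were 73 and 85 spots marked as outliers on the SPAD and SVCD arrays. Repeat spots of a probe were averaged, which left 39425 probes. Probes were named through their transcript accession from a RefSeq gene table (assembly GRCm38.p6, matched without version numbers): 27506 probes (69.8%) matched 20884 gene symbols, and 11919 stayed unnamed. The table gave names only and no coordinates are reported, since the array files use another genome build. A gene was represented by its probe with the highest mean log2 signal; 5512 genes had several probes. Of 851 genes at least 2-fold apart with several detected probes, 775 had every probe in the same direction, and named genes whose probes disagreed, in direction or by at least 1 log2 unit, are given as such. Some probes can also bind near-identical gene copies, which was not tested here.

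With 1 array per group no test was possible and no p-value is given. Genes were counted by size, a log2 difference of at least 1 in either direction, among genes called well above background on both arrays. Of the named genes, 14075 met this on both arrays, 682 on the SPAD array alone, 869 on the SVCD array alone and 5258 on neither. For a gene detected on 1 array, the bright value was set against the higher of the dim probe's own value and the lowest signal of any probe well above background on the dim array, and is given as "at least N-fold". The error of a difference was the SD between repeat spots of the probes printed 10 times on each array, taken by the mean log2 signal of the 2 arrays. It was 0.32, 0.16, 0.09, 0.04, 0.04 and 0.04 in 6 bins of rising signal, and 0.12 over all 279 probes used, and a gene read from several spots has a smaller error. This SD covers spot-to-spot error only, not differences between cultures, RNA extractions or labelling reactions. Drawn 100 times, spot error alone put at most 6 genes past 2-fold. Across genes, which are not independent replicates, the scaled log2 values of the arrays correlated with r = 0.917, and the log2 differences had an SD of 1.21.

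Genes were grouped in 50 lists (pathways, cell type markers and controls) fixed before the data were examined, as were the main values, the size rule, the rule for named genes and all alternatives except spike-in scaling. The median log2 difference of a list's detected genes, with genes detected on 1 array at their bound, was placed among 10000 random lists of the same size matched on mean signal in 20 bins. Positions below the 2.5th or above the 97.5th percentile are called outside the range of random lists; lists with fewer than 5 detected members got no percentile. Of the names in the lists, 3 were not found in the gene table. Lists overlap, as some detected genes also stood in another list. These were 21 of 26 in the mature white adipocyte list, 13 of 21 in the adipokine list and 10 of 23 in the hypoxia list. They were 8 of 21 in the lipid droplet and lipolysis list and 3 of 26 in the macrophage list. In the endothelial list they were 2 of 22, and in the neutrophil and mast cell list 0 of 12. The genes named in the text are the 12 with the largest and the 12 with the smallest log2 difference among genes detected on both arrays, the 5 per direction with the largest bound among genes detected on 1 array, up to 4 members of each list with the largest absolute difference, and Pparg, Cebpa, Fabp4, Adipoq, Lep, Plin1, Slc2a4, Ucp1, Dlk1, Pdgfra and Mki67. Predicted and clone names were left out, which removed 1 name among the higher genes and 0 among the lower. Some genes that the rule takes are not reported here.

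The procedure was tested on simulated data for this comparison with 14083 genes. The simulated noise was the repeat-spot error alone, without differences between cultures, extractions or labelling. All 50 genes changed 2.5-fold, all 50 changed 4-fold and all 50 changed 8-fold were called in the right direction. With so little noise the 2-fold cut largely fixed this in advance, as it did that 0 of 50 changed 1.5-fold were called. Of 13883 unchanged genes, 2 were called, which is not an error rate for the real comparison. Of 200 simulated lists with no shift, 13 fell outside the percentile limits, and 50 of 50 lists shifted by 1 log2 unit were found. Values were shuffled over genes there, so members of a simulated list did not vary together, as those of real lists may. A shift of 1 log2 unit in every member is wide against the usual range of random lists, which largely fixed the second result in advance. Alternatives were quantile normalization, no scaling, cyclic loess, the normexp background correction (offset 50), the authors' table, other filters on dim probes, the mean over a gene's probes, other treatments of genes detected on 1 array and random lists not matched on signal. The normexp alternative used the median spot signal, because the files used here hold no mean signal. Scaling to spike-in controls subtracted from each array the median log2 signal of the 8 of 10 spike-in probes well above background on both arrays. The scanner software's own check marked the slope of signal on spike-in amount as out of range on both arrays (0.847 on SPAD and 0.897 on SVCD). Values were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and with R 4.3.3 and limma 3.58.1 for quantile, loess and normexp, and drawn with matplotlib 3.10.9.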

Results

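Gene expression was measured on 2 single-colour Agilent mouse arrays, 1 per cell population, both derived from the epididymal fat of male mice. Fat was digested with collagenase and the floating cells were spun a further time. The cells that then sedimented were the small proliferative adipocytes, while the stromal vascular cells came from the lower phase of the first spin. Both were grown to 90% confluency, held for 3 days in a medium with insulin, dexamethasone and IBMX, which together induce adipocyte differentiation, and then for 2 days without these. The differentiated small proliferative adipocytes are called SPAD and the differentiated stromal vascular cells SVCD. The sample titles and source names call both differentiated, whereas the short description fields name the populations without that word; the titles and the culture protocol were followed. Each array carried 39429 distinct non-control probes. Signals well above background were found for 25412 of the 39425 probes kept (64.5%) on the SPAD array and for 25868 (65.6%) on the SVCD array, no non-control spot was saturated, and the median local background was 28 on both arrays. The number of arrays, 1 per group, limits the precision: no difference below has a replicate check, and none was tested. The quoted error is an SD of log2 differences between repeat spots, pooled over the repeated probes of similar mean signal on the 2 arrays. It runs from 0.32 for the dimmest probes to 0.04 for the brightest. For a gene read from several spots it was divided by the square root of their number, and is smaller.

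The comparison of SPAD with SVCD addresses how the differentiated progeny of this precursor population differ from those of the stromal vascular fraction. Genes of mature fat cells, endothelial cells, antioxidant defence and the heat shock response were higher in SPAD, whereas genes of cell division, macrophages, mesothelium and contractile myofibroblasts were lower. Car3, a carbonic anhydrase abundant in fat and muscle, was 378-fold higher in SPAD (log2 difference 8.56 ± 0.09), and Cfd, the adipocyte-secreted protease adipsin, 162-fold higher (7.34 ± 0.04). Cd72, a receptor of B cells and macrophages, was 222-fold lower (-7.80 ± 0.09), and Tk1, the thymidine kinase of dividing cells, 161-fold lower (-7.33 ± 0.09). On the dim array the signals were only 20.6 (Car3, SVCD), 50.6 (Cfd, SVCD), 15.4 (Cd72, SPAD) and 19.2 (Tk1, SPAD). The quoted errors, taken at the mean signal of the 2 arrays, understate the spot error of genes so dim on 1 array. Of 14075 genes well above background on both arrays, 2029 (14.4%) were at least 2-fold higher in SPAD and 1875 (13.3%) at least 2-fold lower. Higher genes thus made up 52.0% of the genes past this size. Scaling the arrays to their spike-in controls instead, a choice made after the data were seen, lowered that share to 12.2% and the median log2 difference of all these genes from 0.07 to -0.76.

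**Figure D1:**
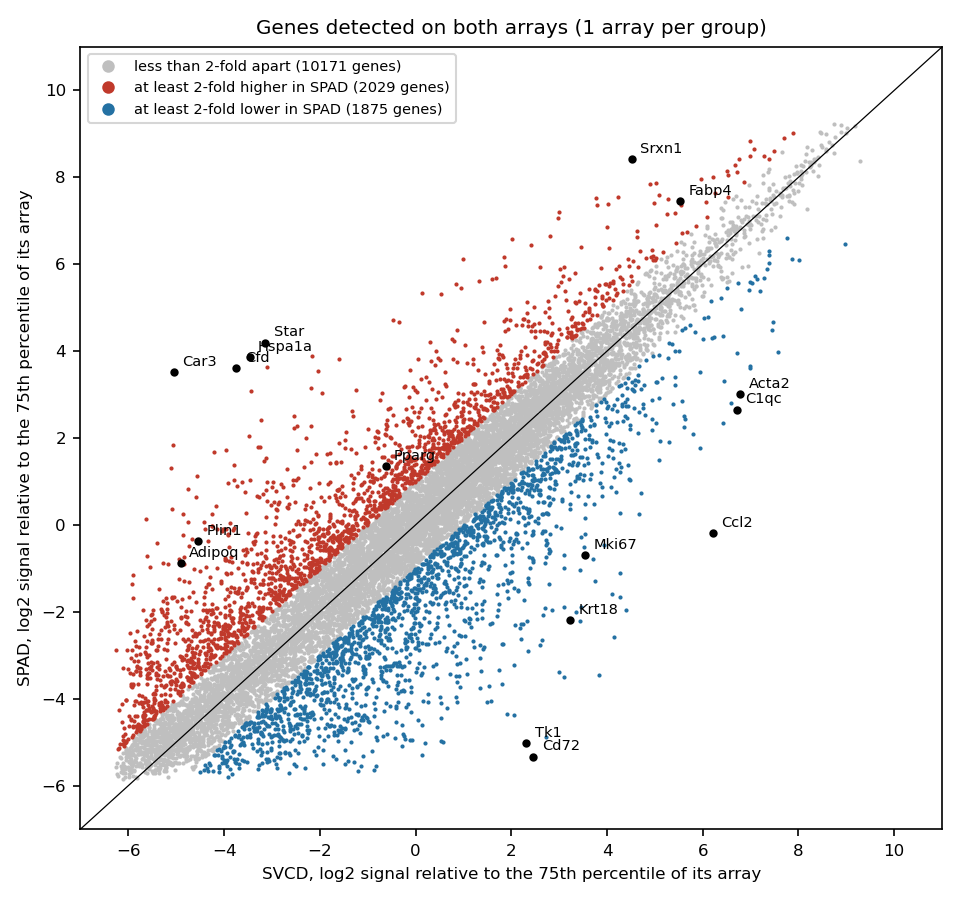
Scaled log2 signal of each of the 14075 genes detected on both arrays, in SVCD (horizontal axis) and SPAD (vertical axis), relative to the 75th percentile of its own array. Red points are the 2029 genes at least 2-fold higher in SPAD, blue points the 1875 at least 2-fold lower, grey points the rest, black points some of the genes named in the text, and the line marks equal scaled signal.

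The other genes with the largest excess in SPAD had varied functions. Star, which carries cholesterol into mitochondria for steroid synthesis, was 161-fold higher (log2 7.33) on its brightest probe, with another at 5.64, and the inducible chaperone gene Hspa1a was also 161-fold higher (7.33). Cyp4b1, a cytochrome P450, had a log2 difference of 6.74, and Ednrb, an endothelin receptor, was 91.7-fold higher. The neurofilament gene Nefm was 85.6-fold higher, and its partner Nefl was detected in SPAD alone, at least 145-fold higher. Depp1 (65.9-fold), the glutathione S-transferase gene Gsta4 (58.9-fold), the growth factor gene Bmp6 (54.9-fold), Slc23a3 (51.9-fold) and Map7d2 (51.3-fold) followed. Among the genes detected in SPAD alone, Sprr2g was at least 697-fold higher. It belongs to a family of cornified envelope protein genes, but its probe carries a noncoding RefSeq entry. The glutathione S-transferase gene Gsta2 was at least 111-fold higher, Nyx at least 97.6-fold and Samd11 at least 78.7-fold.

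At the other end stood, among others, genes of immune cells and of proliferation. Slamf9, a receptor of the SLAM family on immune cells, was 197-fold lower in SPAD, Coro1a, an actin regulator of leukocytes, 106-fold lower, and C5ar1, the receptor for complement fragment C5a, 98.0-fold lower. The nucleotide receptor gene P2ry6 was 81.4-fold lower. The monocyte-attracting chemokine genes Ccl2 and Ccl7 were 85.1-fold and 60.9-fold lower. Ccnd1, the cyclin D that carries cells through G1, was 155-fold lower, the linker histone gene H1f5 86.4-fold lower and the matrix gene Tgfbi 76.6-fold lower. Detected in SVCD alone were the potassium channel gene Kcnn4 (at least 192-fold lower in SPAD), the mitotic kinase gene Pbk (at least 70.1-fold), the prostaglandin-degrading Hpgd (at least 64.0-fold), Aunip (at least 59.2-fold) and the fractalkine receptor gene Cx3cr1 (at least 54.8-fold). In all, 518 of 682 genes detected in SPAD alone and 331 of 869 detected in SVCD alone had a lower bound of 2-fold or more. The scaled log2 floor was higher on the SPAD array (-5.85) than on the SVCD array (-6.30), which makes the bounds of genes detected in SVCD alone smaller. Both counts moved by more than 1.5 times with normexp and with spike-in scaling, so they do not show more genes particular to SPAD.

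Of 26 detected mature white adipocyte genes, 19 were at least 2-fold higher in SPAD and 2 at least 2-fold lower, with a median log2 difference of 1.95, above all 10000 random gene lists of matched signal (percentile 100). Besides Car3 and Cfd, the lipid droplet genes Plin4 and Plin1 were 33.3-fold and 18.0-fold higher, Trarg1, which takes part in glucose transporter trafficking, 24.5-fold, and the adiponectin gene Adipoq 16.2-fold. The insulin-responsive glucose transporter gene Slc2a4 was 7.83-fold higher (log2 2.97 ± 0.05), Pparg, the master regulator of adipogenesis, 3.93-fold higher (1.98 ± 0.01), and the fatty acid carrier gene Fabp4 3.79-fold higher (1.92 ± 0.04). Cebpa, the other central adipogenic regulator, differed by -0.43 ± 0.04, and Lpl, the lipase that frees fatty acids from lipoproteins, was 6.80-fold lower in SPAD (-2.77 ± 0.04). The leptin gene Lep was not well above background on either array. Of the higher genes named here, Plin1, Trarg1, Adipoq and Slc2a4 were rather dim in SPAD too, with signals of 479, 528, 336 and 244. These lie below that array's 75th percentile of 622, whereas Car3, Cfd, Plin4, Pparg and Fabp4 lie above it.

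Lipid droplet and lipolysis genes, 8 of which also stood in another list, were higher: 10 of 21 detected were at least 2-fold higher and none 2-fold lower. Their median was 0.87 (percentile 99.9), or 0.56 with genes detected on 1 array left out and 0.40 with normexp. With spike-in scaling it was 0.04, still at percentile 99.9. The genes with the largest differences, Plin4, Plin1, Adrb3 and Cidec, belong to the mature white adipocyte list too, so the 2 lists are not separate evidence. Cidec, which promotes droplet growth, had a log2 difference of 3.59 on its brighter probe, whereas another Cidec probe had nearly equal signals. Adrb3, the adrenergic receptor of adipocytes, was at least 17.9-fold higher, but its other probe differed by -0.29. Fatty acid and triglyceride synthesis genes lay within the range of random lists (median 0.36, percentile 93.2), with 8 of 23 at least 2-fold higher and 2 at least 2-fold lower. Thrsp, a lipogenic regulator, was at least 39.5-fold higher, Acss2, an acetyl-CoA synthetase, 12.9-fold (log2 2.60 on another probe), and the triglyceride-forming Dgat2 and Dgat1 7.90-fold and 3.45-fold. Adipogenic transcription factors had 7 of 19 genes at least 2-fold higher and 2 lower (median 0.50, percentile 96.6), among them Ebf1 (5.06-fold higher), Cebpd (4.31-fold) and Ebf2 (4.26-fold). The synthesis list lay above the range of random lists without a filter on dim probes (0.65, percentile 99.55) and with genes detected on 1 array left out (0.50, percentile 98.45), and the transcription factor list with the normexp background correction (0.44, percentile 98.5). Scaled to the spike-ins, both medians turned negative. Adipogenesis inhibitors went both ways (3 of 15 higher, 4 lower, median -0.15, mean 0.04, percentile 21.7), and their median was 0.44 with genes detected on 1 array left out and -0.49 without a filter on dim probes, then below the range of random lists (percentile 1.43). The stress-induced Ddit3 was 8.14-fold higher and Zfp521 3.62-fold higher, whereas Klf2 was 3.00-fold lower and Sox9 at least 3.88-fold lower.

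Brown and beige thermogenic genes had 9 of 19 detected members at least 2-fold higher in SPAD and 3 at least 2-fold lower. Their median of 0.52 was within the range of random lists (percentile 92.4) and turned to -0.31 with spike-in scaling. It lay at the upper limit of the range with quantile normalization (0.52, percentile 97.505) and above the range with the normexp background correction (0.39, percentile 99.7). Ucp1, the uncoupling protein that makes brown fat produce heat, was detected in SPAD alone at a dim signal of 190 and was at least 24.1-fold higher. Kcnk3 was 7.81-fold higher and Ppargc1a, a coactivator of mitochondrial biogenesis, at least 6.37-fold. None of the 38 oxidative phosphorylation genes differed 2-fold in the main values, but 28 were below 0. Their median of -0.22 lay below nearly all random lists (percentile 0.47), but within the range of random lists not matched on signal (percentile 3.57). That median was -0.35 with quantile normalization (percentile 0.46) and -1.04 with spike-in scaling (percentile 0.47). Atp5g1 (-0.74 ± 0.04), Ndufb10 (-0.67 ± 0.04) and Atp5a1 (-0.56 ± 0.04) were lower and Ndufa4 (0.64 ± 0.04) higher.

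Genes of other energy and lipid pathways lay within the range of random lists. In the tricarboxylic acid cycle (median -0.14, percentile 11.9), Pcx, which replenishes oxaloacetate, was 13.3-fold higher and Pdhb 2.06-fold higher, while Idh2 was 5.52-fold and Mdh1 2.68-fold lower. Fatty acid oxidation (median -0.18, percentile 10.71) held Ucp3 (3.37-fold lower), Acaa2 (2.98-fold lower), Acot2 (3.17-fold higher) and Cpt1b (3.07-fold higher). Fatty acid uptake and lipoprotein genes (-0.21, percentile 5.33) held Fabp3 (37.9-fold lower), Apoe (5.64-fold lower) and Vldlr (8.49-fold higher). In cholesterol synthesis (-0.22, percentile 10.4), Dhcr7 was 6.18-fold lower, Srebf2 was 2.07-fold lower on its brightest probe but -0.10 on another, and Insig1 was 3.18-fold higher. Glycolysis (0.31, percentile 92.6) and insulin signalling (0.35, percentile 94.0) had positive medians that turned negative with spike-in scaling. Of the glycolytic genes, Eno2 and Aldoc were 2.56-fold and 2.45-fold lower, Pgk1 was 1.81-fold higher, and Pfkp was 1.93-fold higher on its brightest probe but -0.27 on another. The insulin pathway genes Irs2 and Foxo1 were 3.75-fold and 2.49-fold higher.

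Cell cycle genes showed the largest shift of any list. All 36 detected were below 0, 31 at least 2-fold lower in SPAD, with a median of -3.36 (percentile 0). The proliferation marker Mki67 was 18.9-fold lower (-4.24 ± 0.04), the cyclin genes Ccna2 and Ccnb1 49.8-fold and 33.7-fold lower, and Cdk1, the kinase that drives mitosis, 30.7-fold lower, although its other probe gave only -1.13. Cell cycle inhibitors and senescence genes were mixed (5 of 17 higher, 3 lower, median 0.14, percentile 66.1, negative with spike-in scaling). The stress-response gene Gadd45a was 9.44-fold higher and the inhibitor gene Cdkn2b 3.09-fold higher, whereas Cdkn2a and the lamin gene Lmnb1 were 3.27-fold and 5.91-fold lower.

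**Figure D2:**
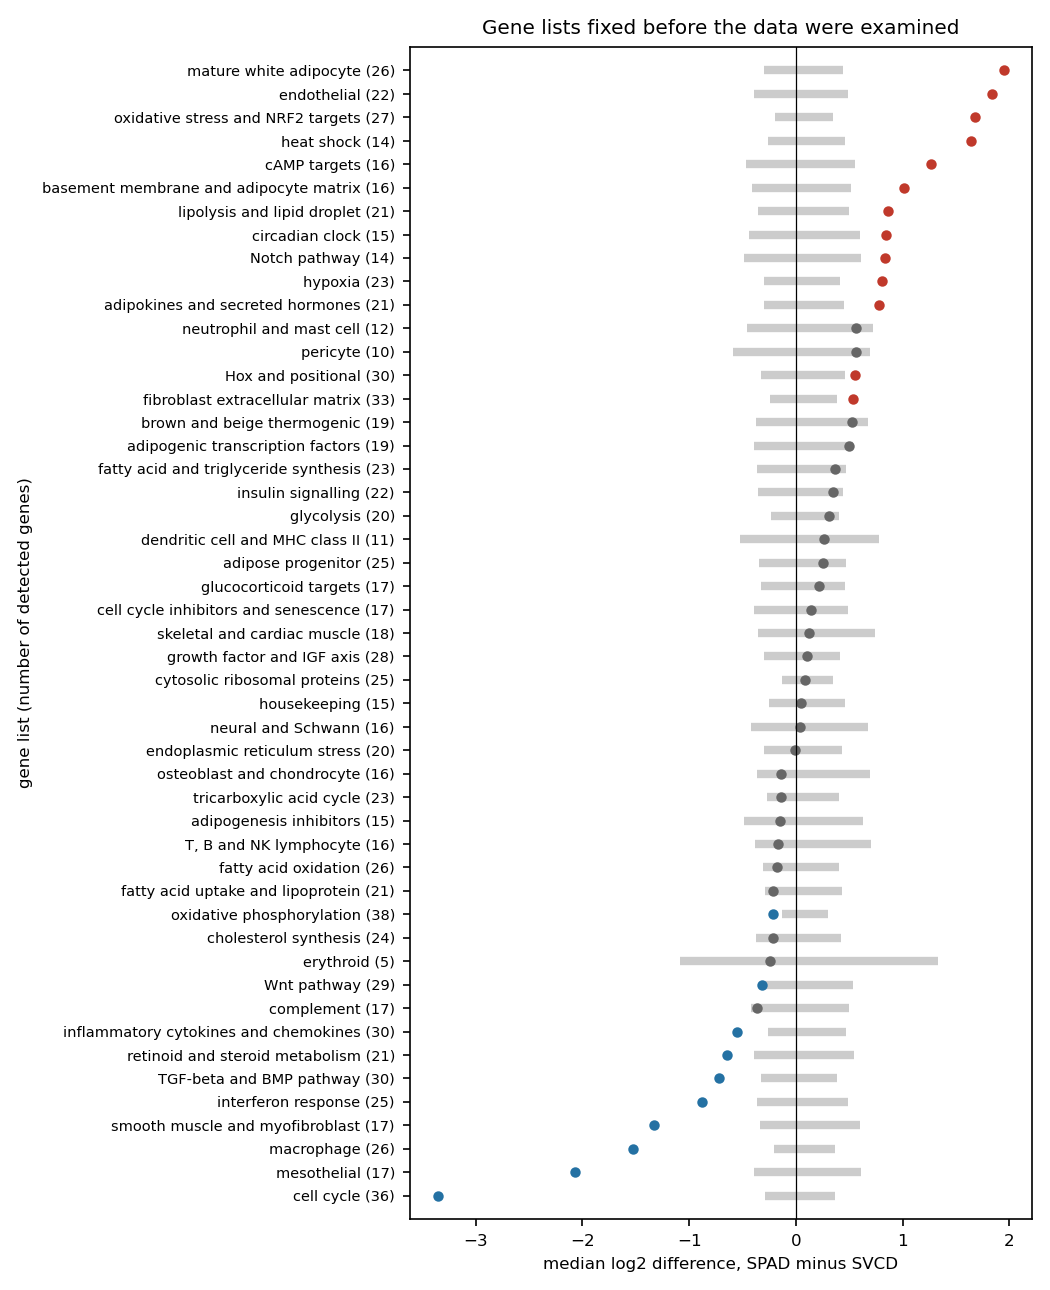
Median log2 difference (SPAD minus SVCD, horizontal axis) of each gene list with at least 5 detected members, the number detected in parentheses. Grey bars span the central range of random lists of matched signal, as defined for the percentiles; red points lie above it, blue points below, and dark grey points within, from cell cycle at -3.36 to mature white adipocyte at 1.95. Spike-in scaling lowers each gene detected on both arrays by 0.83, so that the medians of 20 lists change sign, among them extracellular matrix, adipokines, Hox and hypoxia, while the random lists move down with them.

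Adipose progenitor genes were split, with 7 of 25 at least 2-fold higher and 7 at least 2-fold lower (median 0.26, percentile 83.8, and -0.57 with spike-in scaling). Thy1, a surface marker of mesenchymal cells, was 8.72-fold higher, the microfibril gene Mfap5 4.40-fold and Bmp7 at least 3.63-fold. Vcam1 was 12.2-fold lower on its brightest probe but -0.66 on another. Dlk1, the preadipocyte factor that holds back differentiation, was 2.56-fold lower (-1.36 ± 0.16), and the progenitor receptor gene Pdgfra differed by 0.61 ± 0.03. Fibroblast extracellular matrix genes had a median of 0.53 (percentile 99.7), with 10 of 33 at least 2-fold higher and 4 lower, but of -0.29 with spike-in scaling. Col5a3 was 11.4-fold higher and the thrombospondin gene Thbs2 had a log2 difference of 3.42, while tenascin C (Tnc) was 7.04-fold lower and Col5a2 at least 9.77-fold lower. Basement membrane and adipocyte matrix genes were higher (8 of 16, 1 lower, median 1.01, percentile 99.99), including the laminin genes Lama4 (20.3-fold) and Lama5 (4.25-fold) and the nidogen genes Nid1 (5.93-fold) and Nid2 (4.27-fold).

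Markers of other cell types differed in both directions. Endothelial genes were higher in SPAD (14 of 22 at least 2-fold, 2 lower, median 1.84, percentile 100), among them the vascular transcription factor genes Sox17 (13.3-fold) and Erg (log2 difference 3.43), Robo4 (10.6-fold) and the junction gene Esam (9.41-fold). Macrophage genes were lower (14 of 26 at least 2-fold, 1 higher, median -1.52, percentile 0). Fcgr1 was at least 34.6-fold lower, Aif1 26.4-fold lower and Csf1r, the receptor for macrophage colony-stimulating factor, 16.8-fold lower on its brightest probe, with another at -1.64. Mesothelial genes were lower as well (9 of 17, 1 higher, median -2.07, percentile 0), with the keratin genes Krt8 and Krt18 47.7-fold and 42.7-fold, mesothelin (Msln) 23.5-fold and clusterin (Clu) 17.1-fold lower. The mesothelial median is itself a bound: it was -0.70 with genes detected on 1 array left out (percentile 1.28) and -0.72 with normexp. Smooth muscle and myofibroblast genes followed (11 of 17 lower, 1 higher, median -1.33, percentile 0): calponin (Cnn1) was 40.7-fold lower, smooth muscle actin (Acta2) 13.7-fold and Actg2 11.9-fold lower, and Tagln had a log2 difference of -3.59. Over the genes detected on both arrays the smooth muscle median was -2.24.

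**Figure D3:**
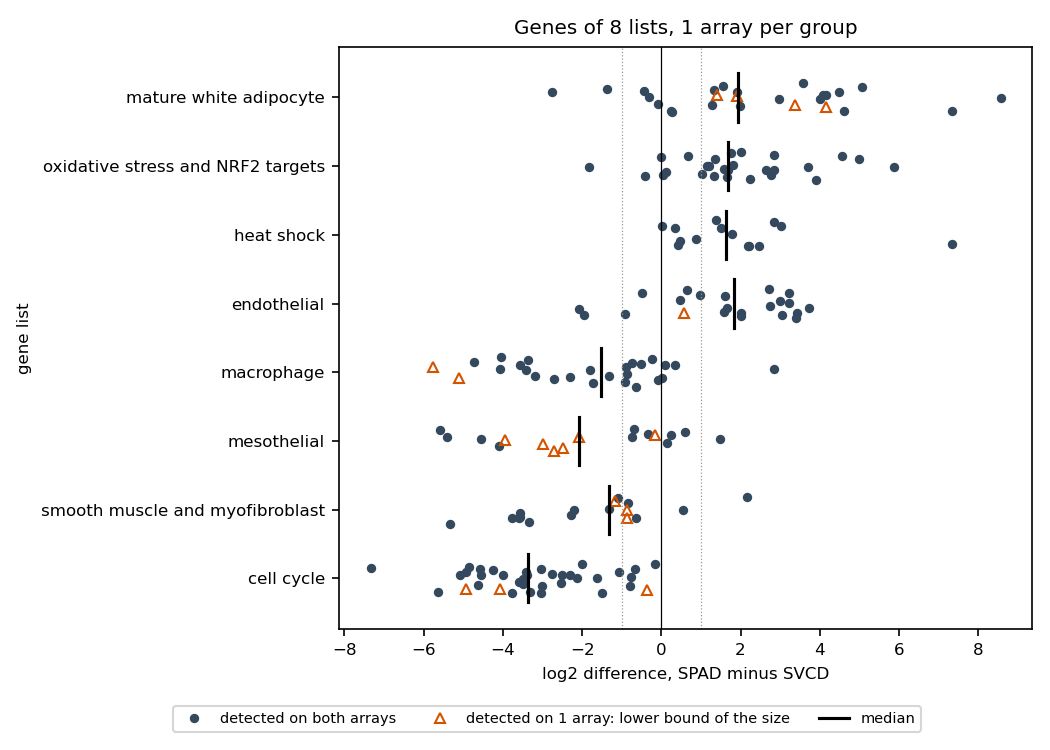
Log2 difference (SPAD minus SVCD, horizontal axis) of each detected gene in 8 of the lists. Filled points are genes detected on both arrays, open triangles lower bounds for genes detected on 1 array, black bars the list medians, and dotted lines mark 2-fold; no cell cycle gene lies above 0, whereas mature white adipocyte genes spread from Lpl at -2.77 to Car3 at 8.56.

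The remaining cell type lists with at least 5 detected members lay within the range of random lists in the main values. Pericyte genes (median 0.56, percentile 94.4) had 4 of 10 higher, such as Rgs5 (7.19-fold), Ndufa4l2 (5.65-fold) and Notch3 (4.31-fold), whereas Anpep was 6.51-fold lower. Neutrophil and mast cell genes (0.56, percentile 93.1) included Kit (10.2-fold higher), the calprotectin gene S100a8 (7.10-fold higher), Fcer1a (at least 6.24-fold lower) and Cma1 (5.42-fold lower). Dendritic cell and MHC class II genes (median 0.26, mean -0.18, percentile 72.2) included Itgax (13.4-fold lower), Batf3 (8.82-fold lower), H2-DMb1 (4.19-fold lower) and H2-Aa (at least 6.13-fold higher); with a mean over each gene's probes they lay above the range (0.83, percentile 98.3). Lymphocyte genes (-0.17, percentile 13.9) held Il7r and Cd28, 5.38-fold and 4.36-fold lower, Gata3, 2.17-fold lower, and Cd79b, 6.52-fold higher. Skeletal and cardiac muscle genes (median 0.12, mean -0.16, percentile 56.3) held Acta1 (14.3-fold lower), Tnni2 (12.9-fold lower), Des (11.9-fold lower) and Ttn (at least 7.17-fold higher), and with genes detected on 1 array left out their median was -1.34, below the range of random lists (percentile 0.04). Osteoblast and chondrocyte genes (-0.14, percentile 13.1) held Col11a1 (at least 32.4-fold lower), osteopontin (Spp1, 4.19-fold lower) and Alpl (at least 5.72-fold higher). Neural and Schwann cell genes (0.04, percentile 44.3) held, with the neurofilament genes, Tubb3 (6.53-fold lower) and Ncam1 (5.51-fold lower on its brightest probe, -0.91 on another). The positive medians among these lists all turned negative with spike-in scaling, and that of the neural list also under quantile, loess and no scaling and with genes detected on 1 array left out (-0.09). Without a filter on dim probes, the medians of the osteoblast and lymphocyte lists turned to 0.45 and 0.22, both within the range of random lists. The median of all genes was 0.25 under that setting. Erythroid genes (-0.24, percentile 23.1) had 5 detected members, among them Epor (3.04-fold lower), Alas2 (at least 1.88-fold lower) and Hba-a2 (2.06-fold higher), and a median of 0.05 with normexp and 0.45 without a filter on dim probes. Only 4 of 22 epididymis and male germ cell genes were detected, none of them 2-fold apart (median -0.03, or 0.03 with normexp).

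Of the stress-related lists, oxidative stress and heat shock were among the most shifted, whereas endoplasmic reticulum stress lay within the range of random lists. Of 27 detected oxidative stress and NRF2 target genes, 21 were at least 2-fold higher in SPAD and 1 at least 2-fold lower (median 1.68, percentile 100). Besides Gsta4, the cystine importer gene Slc7a11 was 31.9-fold higher, Gclc, which catalyses the limiting step of glutathione synthesis, 23.6-fold, and the sulfiredoxin gene Srxn1 14.9-fold. All 14 heat shock genes were above 0 and 9 at least 2-fold higher (median 1.64, percentile 100), including Hspb8 (8.08-fold), Dnajb1 (7.20-fold) and Hsph1 (5.57-fold). Hypoxia genes had 9 of 23 higher and 2 lower (median 0.81, percentile 99.98, but -0.02 with spike-in scaling), with Adm 15.0-fold, Ndrg1 7.43-fold and the oxidase gene Ero1a 6.87-fold higher and Car12 at least 6.48-fold lower. Endoplasmic reticulum stress genes had a median of -0.01 and a mean of 0.70 (percentile 35.5), since 7 of 20 were at least 2-fold higher and none lower. The 7 included Chac1 (10.4-fold) and Trib3 (6.03-fold), which act with Ddit3 in the amino acid stress response.

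Inflammatory and interferon lists were shifted to lower values in SPAD. Inflammatory cytokine and chemokine genes had 12 of 30 at least 2-fold lower and 7 higher (median -0.55, percentile 0.04, or -0.24 with normexp), among them Ccl4 (41.0-fold lower) and the interleukin 1 receptor antagonist gene Il1rn (37.3-fold lower). Interferon response genes had 12 of 25 lower and 3 higher (median -0.88, percentile 0.01, or -0.56 with normexp). Oasl2 was 7.17-fold, Gbp3 6.25-fold and Ifit2 at least 3.56-fold lower, whereas Ifi44 was at least 5.81-fold higher. Complement genes lay within the range (3 of 17 higher, 7 lower, median -0.37, percentile 3.87) and held C3ar1, 28.1-fold lower, and C1qc, 16.6-fold lower, beside C5ar1 and the higher Cfd.

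Secreted factors and signalling pathways differed as follows. Adipokine and hormone genes had 10 of 21 higher and 5 lower (median 0.78, percentile 99.9, but -0.05 with spike-in scaling). They lay within the range of random lists with normexp (0.32, percentile 96.4). Of these genes, the chemerin gene Rarres2 was 37.3-fold and the resistin gene Retn 22.6-fold higher, with a log2 difference of 5.74 on another Retn probe. TGF-beta and BMP pathway genes were lower (12 of 30, 4 higher, median -0.72, percentile 0), although Bmp2 was 14.0-fold higher, like Bmp6, while the BMP antagonist gene Grem1 was 11.8-fold lower. Wnt pathway genes had 9 of 29 lower and 5 higher (median -0.31, percentile 1.88), with Ccn4 20.1-fold, Sfrp2 at least 10.5-fold, Fzd2 5.29-fold and Wnt5a 5.22-fold lower. The Wnt list lay within the range of random lists with a mean over each gene's probes (percentile 2.98) and with genes detected on 1 array left out (percentile 6.54). Notch pathway genes had 6 of 14 higher and 1 lower (median 0.83, percentile 99.6, but 0.004 with spike-in scaling), with Dll4 7.20-fold, Jag2 6.46-fold and Notch1 6.42-fold higher and Lfng at least 18.7-fold lower. Growth factor and IGF axis genes were mixed (10 of 28 higher, 8 lower, median 0.11, percentile 61.0, negative with spike-in scaling and no scaling). Gdnf and Angpt2 were 19.7-fold and 12.3-fold higher, Hgf was 16.3-fold lower, and Igf1 was 12.2-fold lower on its brightest probe, with a log2 difference of -6.96 on another.

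Genes that respond to cAMP were higher (10 of 16, 2 lower, median 1.26, percentile 100), with the phosphodiesterase gene Pde4b 11.2-fold and Pck1, which makes phosphoenolpyruvate for glyceride synthesis, at least 10.4-fold higher, but Rgs2 6.24-fold lower. Glucocorticoid targets lay within the range of random lists (4 of 17 higher, 1 lower, median 0.22, percentile 79.8, negative with spike-in scaling). Of these, the metallothionein gene Mt2 was 3.59-fold and Ddit4 3.40-fold higher, and Hif3a was 7.03-fold higher on its brightest probe but -1.41 on another. Circadian clock genes had 6 of 15 higher and 1 lower (median 0.84, percentile 99.7, but 0.015 with spike-in scaling), including Cry2 (6.29-fold), Ciart (5.63-fold) and Nr1d2 (3.69-fold), against Per2, at least 3.19-fold lower. Hox and positional genes had 10 of 30 higher and 1 lower (median 0.56, percentile 99.0, but -0.27 with spike-in scaling), with Nr2f1 5.65-fold, Hoxd3 at least 4.66-fold and Hoxd9 3.08-fold higher, and a log2 difference of 1.32 for Hoxa11. Retinoid and steroid metabolism genes had 7 of 21 higher and 7 lower. Their median of -0.64 lay low among random lists (percentile 0.35), but their mean was 0.35, and the list lay within the range with normexp (-0.12), with a mean over each gene's probes (-0.32), with genes detected on 1 array left out (-0.14) and without a filter on dim probes (0.32). Next to Star and Rarres2, Akr1c18 was 15.8-fold and Adh7 at least 15.0-fold higher.

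Cytosolic ribosomal protein genes (median 0.08, percentile 44.6) and housekeeping genes (median 0.05, percentile 42.9) lay within the range of random lists, and both medians turned negative under quantile, loess, spike-in and no scaling, the ribosomal one also with a mean over each gene's probes. None of the 25 ribosomal genes differed 2-fold, with Rpl3 at -0.72 and Rplp0, Rpl5 and Rps2 at 0.52, 0.47 and 0.43. Of the housekeeping genes, Gusb and Tfrc were 2.71-fold and 2.39-fold lower, and the actin gene Actb differed by -0.92. Over all lists, 23 of the 49 with at least 5 detected members lay outside the central range of random lists. By chance 2.45 would be expected if the genes of a list varied independently of each other, as those of random lists do. Genes of a list that vary together would place more lists outside, so 23 against 2.45 does not measure an effect of the population. Random-list percentiles describe these 2 arrays only, and several genes belong to more than 1 list.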

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

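The macrophage marker pattern and all tests of explanations in this part were chosen after the values were seen. The spike-in controls, used above only for an alternative scaling, and the probes without a gene name, which enter no comparison above, drew attention because both differed between the arrays.

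Of 26 detected macrophage markers, 22 were lower in SPAD and 4 higher, by very different amounts. Among the 24 detected on both arrays the log2 difference ran from -4.72 to 2.85, and 12 were higher or less than 2-fold lower. Complement and receptor genes, chosen after their values were seen, were far lower (C1qa -3.19, C1qb -3.37, C1qc -4.06, Csf1r -4.07, Mrc1 -2.72), whereas abundant genes shared by myeloid cells differed less (Tyrobp -0.90, Fcer1g -0.75, Ctss -0.65, Laptm5 -0.50) and Lyz2, with signals of 98429 in SPAD and 84459 in SVCD, by 0.35. A smaller share of the same macrophages as the only cause would give about 1 common difference; the SD over the 24 markers detected on both arrays was 1.80, but the spread between cultures was not measured, so this decides nothing and a smaller share stays open. A larger share of adipocyte-lineage cells would dilute every other cell type. The mesothelial and smooth muscle medians of -2.07 and -1.33 went that way, and the remaining cell type lists lay within the range of random lists. The endothelial median of 1.84 argues only against dilution as the sole cause. Dilution together with a separate rise in endothelial cells stays open. Other myeloid cells in SPAD could supply the shared genes, with the neutrophil and mast cell list high but within the range of random lists at percentile 93.1, and with 1 array per population this cannot be told apart from a smaller share or from macrophages in another state, which were not tested.

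The spike-in control probes had a median log2 signal 0.71 higher on the SPAD array before scaling, a 1.64-fold difference. The difference was between 0.65 and 0.77 in all but 1 of the 8 detected probes, the exception being 1.76. A brighter SPAD array as a whole would raise the genes too, but the 75th percentile of gene signal was lower on that array, the log2 difference being -0.13. Less polyadenylated RNA per amount of labelled RNA in SPAD, or more spike-in added to that sample, could each give this pattern; both predict the same median of all genes after spike-in scaling, -0.76, and with 1 labelling per group they cannot be told apart.

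Among probes without a gene name, 846 were at least 2-fold higher in SPAD and 403 at least 2-fold lower, so that 67.7% of those past this size were higher. Named probes drawn to the same signal reached 57.4% at the upper limit of the central range of 1000 draws (median 55.0%), which argues against the lower signal of unnamed probes as the whole cause. Named noncoding RefSeq transcripts showed the same lean, with 102 higher and 36 lower (73.9%), where coding transcripts drawn to their signal gave a median of 53.8%, with a central range of draws from 46.0% to 61.4%. A candidate explanation is that noncoding transcripts among the unnamed probes are higher in SPAD, a hypothesis found and tested on the same data. The unnamed transcripts themselves were not identified here.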

How the results depend on the processing

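Spike-in scaling was chosen after the data were seen; the other alternatives were planned. Lists outside the range of random lists numbered 17 to 24, and between 16 and all 23 of the main ones stayed on the same side, the 17 and the 16 both under the brighter-probe filter discussed below; spike-in scaling, no scaling and the authors' table shift the genes detected on both arrays alike, so list positions could move there only through genes detected on 1 array. The count of genes 2-fold higher stayed within 1.5 times of 2029 under 7 alternatives (1378 to 2648) and that of genes 2-fold lower within 1.5 times of 1875 under 8 (1331 to 2627). With spike-in scaling 740 genes were 2-fold higher and 5303 lower, because each counted gene is lowered by 0.83, and the list medians became 1.12 for mature white adipocyte, -0.31 for thermogenic, -0.57 for progenitor, -0.29 for extracellular matrix, -0.052 for adipokines, -0.27 for Hox and -0.020 for hypoxia genes. Without a filter on dim probes 20884 genes were counted instead of 14075, and 3370 were 2-fold higher. The median log2 difference of all genes was then 0.25, and the retinoid and steroid median was 0.32. The added genes were not well above background on both arrays, and the scaled log2 floor was higher on the SPAD array (-5.85 against -6.30). Positive medians under this setting are therefore to be read against 0.25, and the cause was not tested further. Restricted to genes above the median detected signal on both arrays, 838 genes were 2-fold higher and 719 lower, as only 7779 genes were counted, and the medians were -0.080 for mature white adipocyte (7 members), -0.28 for adipokines, 0.14 for Wnt (5 members), 0.37 for retinoid and steroid (5 members) and 0.83 for extracellular matrix genes. That filter drops genes dim on 1 array, and so those with large differences, such as Cfd and Krt18; its medians and list positions therefore do not test the shifts, and leaving out genes detected on 1 array is selective in the same way. Without scaling, the medians were 1.82 (mature white adipocyte), 0.40 (thermogenic), 0.13 (progenitor) and 0.41 (extracellular matrix), again by a common shift. The mature white adipocyte median was 1.83 with quantile normalization and 1.67 with normexp, and the thermogenic median was 0.39 with normexp. The cause of these moves was not tested. With measured differences in place of bounds the mature white adipocyte median was 2.47, since a bound is never larger in size than the measured difference. For lists, the alternative of genes detected on at least 1 array is the same calculation and no separate check. None of the 196 named genes at least 2-fold apart changed direction under the 7 alternatives run for single genes. Spike-in scaling, no scaling and the authors' table shift genes detected on both arrays alike, by less than 1 log2 unit. They could therefore turn none of those genes and do not test their direction. Genes detected on 1 array entered at a bound, which cannot pass 0 for a single probe, so the direction of those genes was not tested either. Of all 215 named genes, 7 changed sign with spike-in scaling and 1 with normexp. No paired analysis was possible because each group has 1 array, and for the same reason neither a replicate could be left out nor the slide fitted as a block. Signal over background limits dim genes most, as repeat spots differed by an SD of 0.32 there.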

Other observations

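The gene families in this part, and their percentiles, were chosen after the values were seen. Proteasome genes parted by type. The 3 subunits of the immunoproteasome, the interferon-induced form that trims peptides for MHC class I, were lower in SPAD (Psmb8 -2.29, Psmb9 -2.06, Psmb10 -2.58). Of 34 other proteasome subunit genes, 33 were above 0, with a median of 0.58 at percentile 99.98 of random lists, although spike-in scaling turned that median to -0.25. Glutathione S-transferase genes, which conjugate electrophiles to glutathione, were at least 2-fold higher in 14 of 20 cases and 2-fold lower in 0 (median 1.60).

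Of 13 alpha and beta tubulin genes, 7 were at least 2-fold lower and 0 at least 2-fold higher (median -1.32). Histone genes of the H2ac, H2bc, H3c and H4c series and the linker histone genes H1f1 to H1f5 had 19 of 40 at least 2-fold lower and 5 higher (median -0.79), with 13 above 0. The Rhox homeobox genes, a cluster best known from reproductive tissues, had 8 of 13 at least 2-fold higher in SPAD and 1 lower (median 1.23). Histone and Rhox genes have near-identical copies, so probes of 1 gene can carry signal of another and the counts are uncertain to that extent.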
